A study of Rattus norvegicus with 48 samples.

How the data were processed

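Messenger RNA was profiled on 48 single-colour Illumina rat arrays from male F-344 rats in a model of chemically induced liver cancer. Per the labels' protocols, rats of the lesion groups received 150 mg/kg of the carcinogen diethylnitrosamine and recovered for 2 weeks. They then ate a diet with 0.02% 2-acetylaminofluorene for 1 week and underwent partial hepatectomy with 1 further week on the diet. The labels list no such treatment for the controls. Lesions were cut by laser capture from frozen sections stained with hematoxylin and eosin, and total RNA was turned into biotinylated complementary RNA for hybridization. The groups were taken from the sample titles: 10 control livers, 10 nodules labelled KRT19-positive, 10 nodules labelled KRT19-negative, 4 adenomas, 5 early hepatocellular carcinomas (eHCC) and 9 advanced hepatocellular carcinomas (aHCC). How the KRT19 status of a nodule was assigned, and the age of the control rats, were not given in the sources used here.

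The deposited table held 1 intensity and 1 detection p-value for each of 22523 probes in each array, made with BeadStudio 3.0.19.0 per the submitters' processing notes. Although deposited as non-normalized, the intensity values had nearly the same distribution in all 48 arrays, with medians between 159.0 and 159.6, so the deposited values were quantile-normalized intensity on a linear scale. Background had not been subtracted, since the lowest intensity was 96.8 and a probe with a detection p-value near the middle of its range had an intensity of 139. The second deposited table of the same arrays was identical, with a largest difference of 0. The deposited detection p-value came in steps of 1 in 825, as a rank among that many negative control beads would give. The reference annotation used for probe design was not given in the sources used here. Micro-RNA arrays were not analysed here.

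Intensities were converted to log2 with no further normalization. The design had foreseen normexp background correction with quantile normalization (neqc in limma) on raw intensities; because the values were normalized already, log2 of the deposited intensity became the main setting and neqc was kept as an alternative. Uncorrected background shrinks the fold of dim genes. For Abcc3 in nodules labelled KRT19-positive, the fold over control was 16.9 on the deposited values and 35.8 after neqc. Bright genes were limited at the other end, because the highest intensity of any probe was 15.54 on the log2 scale. Gstp1 lay within 0.5 of that level in 26 of 38 lesion arrays and Gclc in 14, so their folds may be understated.

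Probes were kept when their detection p-value was under 0.05 in at least 4 arrays, which left 13679 probes. Of all probes in the table, 13793 had 1 gene symbol, 0 had several and 8730 had none. Symbols were checked through 13752 gene identifiers that matched the RefSeq table of the GRCr8 rat assembly, and 0 symbols changed. The probe with the highest mean log2 intensity stood for each gene, which gave 9273 genes and 4206 unnamed probes, together 13479 features. For 189 genes with more than 1 kept probe the other probes were compared, and disagreements are given beside the genes named.

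All 6 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), so that the groups of 4 and 5 arrays shared the spread estimated over all groups. P-values were adjusted by the Benjamini-Hochberg method over all features within each of 9 comparisons, and a gene passed at an adjusted p under 0.05. Gene lists, 33 in number, were tested with camera at its preset correlation of 0.01 and adjusted over the lists within a comparison. Each list was also tested with a correlation estimated from the data. Fold changes come from differences of mean log2 intensity, errors are standard errors (SE) of the fit, and group levels are means ± SD. A gene detected in no array of a group has a lower bound in place of a fold, taken in each of those arrays against its lowest intensity among detected probes or the probe's own intensity, whichever was higher. Named genes were the 5 or 10 largest rises and falls among those that passed in a comparison, the members of the described lists with the 2 largest rises and falls, and Krt19, Gstp1, Nqo1, Gclc, Afp, Nfe2l2 and Keap1 throughout. Provisional symbols were not named. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

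A signature score was the slope of a nodule's log2 difference from the control mean on the aHCC minus control difference. It was taken over the genes that passed between aHCC and control. The score is 0 at the mean of the controls and 1 at the mean of the aHCC, is not bounded by them, and gives most weight to genes with large aHCC changes. Labels were compared by a two-sided permutation test with 100000 resamples over all nodules and by exact permutation tests within runs. The share of aHCC changes found in nodules counted genes that passed in both comparisons in the same direction. Because both comparisons use the same controls, unchanged groups were simulated against simulated controls 20 times, and the overlap of independent lists was computed per direction.

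Sample numbers in the labels ran from 1 to 48 with controls at the end of 3 stretches. These were treated as runs A (1 to 14), B (15 to 27) and C (28 to 48), and values with the run as a block and within runs were planned. The array type carries 12 arrays per chip, so sets of 12 consecutive numbers were added as a second block after the data had been seen. The chip of each array was not given in the sources used here. Set 1 held 10 nodules and 2 controls, set 2 held 10 nodules and 2 controls, set 3 held 9 aHCC and controls 25 to 27, and set 4 held the adenomas, the eHCC and controls 46 to 48. Other alternatives were normexp with an offset of 50, scaling to the 75th percentile with a floor of 16, the second deposited table, no detection filter, a stricter filter at a detection p under 0.01, a trended robust variance, array weights, only the groups compared, the mean of all probes of a gene, and each array left out in turn. Leaving out aHCC replicate 29 together with the set block, leaving out controls 25 to 27, and neqc were added after the data had been seen.

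The gene fit was tested for 5 of the comparisons on simulated data with 200 changed genes among 13479. At a log2 change of 1 the fit recovered 98.5% of changed genes between the nodule labels, 85.1% between eHCC and adenoma, 94.0% between aHCC and eHCC and 91.0% between aHCC and control. Noise was normal and independent, changed genes were drawn at random, and no batch, shared animal or mixed group was simulated. The recovery therefore does not carry over to genes with a wide spread. Between eHCC and adenoma 100% were recovered at a log2 change of 2, yet Cyp2c11 at −2.58 ± 0.86 SE did not pass in the data. Between 8323 and 11434 probes were detected per array, and the number of arrays limits the precision. Captured regions may share an animal. The labels do not tie regions to animals, so p-values measure the spread between these samples and may be too small wherever regions came from the same rat. No sample was left out of the main comparisons.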

Results

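Gene expression was measured in 48 laser-captured samples of rat liver, 1 array each, from the earliest visible lesions of a chemically induced model to advanced cancer. Samples came from 10 control livers, 20 nodules taken 10 weeks after initiation with diethylnitrosamine, 4 adenomas and 5 early carcinomas (eHCC) at 10 months, and 9 advanced carcinomas (aHCC) at 14 months. The nodules carried 1 of 2 labels, KRT19-positive (10) or KRT19-negative (10), after keratin 19, a keratin of bile ducts and liver progenitor cells. Mean numbers of detected probes per array ranged from 9238 ± 391 (SD, n = 10) in control liver to 10618 ± 504 (SD, n = 5) in eHCC. The comparisons ask which genes change at each stage, whether targets of the oxidative stress regulator NRF2 are among them, and whether the changes of advanced cancer are already present in the nodules. Lesions may share an animal and the labels do not tie regions to animals, so the p-values below measure the spread between these samples and may be too small. Controls were of unstated age, so stage and age of the rats were not separated in any comparison with control. The labels list the carcinogen, diet and hepatectomy for the lesion groups and list none for the controls. No group was labelled as treated liver without a lesion, so lesion and treatment were not separated either.

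Krt19 was read first in every nodule because it checks the labels. In run A (samples 1 to 14) the 5 nodules labelled KRT19-positive had a log2 Krt19 intensity of 11.64 to 13.15 and the 5 labelled KRT19-negative 7.69 to 10.50. In run B (samples 15 to 27) the order was opposite, with 7.70 to 10.60 in the 5 nodules labelled KRT19-positive and 11.49 to 12.96 in the 5 labelled KRT19-negative. Over both runs the mean was 10.58 ± 1.81 (SD, n = 10) under the positive label and 10.93 ± 1.83 (SD, n = 10) under the negative label, against 7.83 ± 0.39 (SD, n = 10) in control liver. The transcript thus went against the label in run B, and every direction drawn from the labels carries that reservation.

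**Figure D1:**
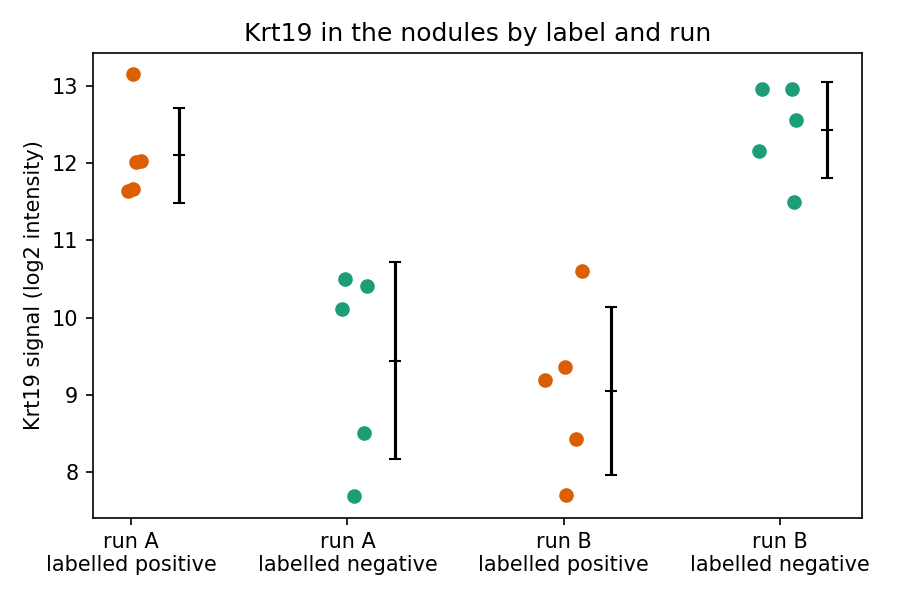
Krt19 log2 intensity (vertical axis) of each nodule, by label and run (horizontal axis, 5 nodules per column). Points are nodules and bars are the mean ± SD; nodules labelled KRT19-positive sit above those labelled KRT19-negative in run A and below them in run B.

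In nodules labelled KRT19-positive, enzymes that detoxify electrophiles stood far above control liver. Gstp1, the placental glutathione transferase long used to mark rat liver lesions, was 63.2-fold higher (log2 change 5.98 ± 0.38 SE, 10 and 10 arrays, adjusted p = 3.32e-16 by limma), and the aflatoxin aldehyde reductase Akr7a3 was 24.6-fold higher (4.62 ± 0.29 SE). Akr1b8, an aldo-keto reductase, rose 23.0-fold and Nqo1, a quinone reductase, 12.0-fold. The export pump Abcc3 rose 16.9-fold. Of 32 measured NRF2 targets 25 rose and 0 fell (26 rose adjusted over the list alone), with a median log2 change of 1.27; the list passed with an adjusted p = 0.0126 with an estimated correlation. Keap1, the repressor of NRF2, differed by 0.24 ± 0.10 SE on the log2 scale (adjusted p = 0.0926 by limma) and Nfe2l2, which encodes NRF2, by 0.07 ± 0.16 SE (adjusted p = 0.825 by limma). Nfe2l2 was lower within run B (−0.36 ± 0.09 SE, adjusted p = 0.0101 by limma), where nodules of set 2 were read against controls of set 3. It was not called lower within set 2. The controls of set 3 differed from the other controls in 710 genes (limma), so the run B call may rest on them. Keap1 passed without KRT19-positive nodule replicate 4 (0.29, adjusted p = 0.0475 by limma) or without control liver replicate 13 (0.29, adjusted p = 0.0447 by limma). Of 7 NRF2 pathway regulators 4 rose and 0 fell (5 rose adjusted over the list alone; adjusted p = 0.0690 with an estimated correlation). Among 11 markers of foci and nodules 9 rose and 0 fell (9 rose and 1 fell adjusted over the list alone), and that list also passed with an adjusted p = 0.0148 with an estimated correlation. It shares members with the NRF2 targets, among them Gstp1, Akr7a3 and Akr1b8, so the list results are not independent. Krt19 was 6.70-fold higher than in control (2.75 ± 0.70 SE, adjusted p = 0.00363 by limma). The antimicrobial peptide gene Defb1 was detected in 9 of 10 nodules and in 0 of 10 controls, at least 17.2-fold higher.

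Several metabolic and secreted-protein genes of hepatocytes were lower in the same nodules. Obp3, a male urinary-type globulin made by liver, was 9.86-fold lower (log2 change −3.30 ± 0.52 SE, 10 and 10 arrays), the liver-intestine cadherin Cdh17 8.66-fold lower (−3.12 ± 0.40 SE) and the aldehyde oxidase Aox3 7.45-fold lower (−2.90 ± 0.25 SE). Angptl4, an inhibitor of lipoprotein lipase, was 6.34-fold lower, but its other probe changed by only −0.48. Of 18 growth hormone regulated genes 10 fell and 2 rose (12 and 2 adjusted over the list alone); Cyp2c12, a P450 of female rat liver, was 6.02-fold higher while Cyp2c11, its male counterpart, was 4.40-fold lower. That list had an adjusted p = 0.133 with an estimated correlation. In fatty acid oxidation 10 of 22 genes fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.0923 with an estimated correlation), among them the fatty acid hydroxylase Cyp4a2, 5.22-fold lower. Bile acid synthesis and transport had 6 of 15 genes lower and 0 higher (10 and 1 adjusted over the list alone), including the bile acid ligase Slc27a5 (3.99-fold) and the hydroxylase Cyp8b1 (3.90-fold); this list had an adjusted p = 0.306 with an estimated correlation. Complement and coagulation had 6 of 22 genes lower and 0 higher (7 adjusted over the list alone; adjusted p = 0.461 with an estimated correlation), and amino acid catabolism and the urea cycle 6 of 20 lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 0.463 with an estimated correlation). Of 22 P450 genes 7 fell and 3 rose (8 and 3 adjusted over the list alone; adjusted p = 0.554 with an estimated correlation). In lists that did not pass in the pooled fit, 1 of 15 secretory products fell and 0 rose (adjusted p = 0.597), 1 of 17 acute phase genes rose and 1 fell (adjusted p = 0.576), and 5 of 16 hepatocyte transcription factors fell and 1 rose (adjusted p = 0.0866, and 0.00235 with the set block). In cell cycle and proliferation 12 of 34 genes rose and 0 fell (15 rose adjusted over the list alone; adjusted p = 0.344 with an estimated correlation), with cyclin B2 (Ccnb2) 2.57-fold higher. Markers of other cells moved as well. Of 13 biliary and progenitor markers 6 rose, including Cd24 (4.72-fold), and of 23 extracellular matrix genes 9 rose and 2 fell, including the collagen chain Col1a2 (3.11-fold higher), while 2 of 10 blood cell markers fell and 0 rose. With an estimated correlation those 3 lists had an adjusted p = 0.180, 0.344 and 0.269.

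The pooled changes covered unlike runs, and for some genes part of the contrast between runs may lie in the controls. Run B holds nodules of set 2, but its only controls, 25 to 27, lie in set 3. Those controls differed from the other controls in 710 genes (limma), with Gstp1 higher by 1.03 ± 0.18 SE on the log2 scale. Within run A the log2 changes of Gstp1, Akr1b8, Nqo1 and Krt19 were 6.83, 6.18, 4.33 and 4.19, and within run B 4.91, 2.99, 2.88 and 1.12, the last of which did not pass (adjusted p = 0.127 by limma). Obp3, Cyp2c11 and Cyp2c12 changed by −5.87, −3.79 and 4.22 within run A and by −1.36, −0.54 and 0.92 within run B, where Cyp2c11 and Cyp2c12 did not pass (adjusted p = 0.303 and 0.248 by limma). Controls 13 and 14, in the set of the run B nodules, had log2 Obp3 of 14.44 and 13.72, against 12.63 to 13.56 in controls 25 to 27. For Cyp2c11 the values were 15.51 and 15.29, against 14.90 to 14.98. Akr1b8 lay at 7.27 to 7.56 in controls of run A and 7.45 to 7.72 in those of run B. In the nodules it lay at 13.20 to 14.26 and 8.47 to 12.57. Nqo1 lay at 9.53 to 9.78 and 9.27 to 9.48 in the controls, and at 13.68 to 14.27 and 11.61 to 13.58 in the nodules. For Akr1b8 and Nqo1 the contrast between runs thus lay mainly in the nodules. Defb1 rose by 6.33 within run A and by 2.41 within run B, and Cyp8b1 fell by −3.07 and −0.75, with neither passing within run B (adjusted p = 0.0545 and 0.202 by limma). Slc27a5 changed by only −1.06 within run B, and passed. Lists that passed numbered 8 within run B, against controls 25 to 27. Afp, lower by −0.73 ± 0.29 SE (adjusted p = 0.0657 by limma), passed without KRT19-positive nodule replicate 21 or 24 (adjusted p = 0.0479 and 0.0498 by limma) and within run A (−1.11 ± 0.17 SE, adjusted p = 0.000119 by limma).

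In all, 2517 genes differed between nodules labelled KRT19-positive and control (1306 higher, 1211 lower; limma, adjusted p under 0.05), 2211 with the run as a block, and 1517 with sets of 12 as a block, of which 1269 were shared in direction with the pooled calls. The count was 3372 within run A and 3295 within run B, 2429 within set 1 and 1290 within set 2. Among genes that passed, Krt19, the P450 Cyp3a23-3a1, Slc27a5, Cyp8b1 and Ccnb2 no longer passed with the set block (adjusted p = 0.0635, 0.0745, 0.0625, 0.0536 and 0.0683 by limma). Of 33 lists 18 passed, 2 of them also with an estimated correlation, and 17 of the 18 passed with the set block, when the blood cell list did not.

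Nodules labelled KRT19-negative showed the same leading genes against control liver. Gstp1 was 42.2-fold higher (log2 change 5.40 ± 0.38 SE, 10 and 10 arrays, adjusted p = 9.99e-15 by limma), Akr1b8 24.4-fold (4.61 ± 0.57 SE), Akr7a3 19.1-fold and Nqo1 11.5-fold. The carbonic anhydrase Car2 rose 20.3-fold, and Defb1 was again detected in 9 of 10 nodules and no control, at least 17.5-fold higher. Of 32 NRF2 targets 24 rose and 0 fell (26 rose and 1 fell adjusted over the list alone), and the list kept an adjusted p = 0.0172 with an estimated correlation. The 11 foci and nodule markers, of which 8 rose and 0 fell (9 rose adjusted over the list alone), also kept an adjusted p = 0.0172 with an estimated correlation. These markers share members with the NRF2 targets. Krt19 was 8.58-fold higher (3.10 ± 0.70 SE, adjusted p = 0.00107 by limma). Keap1 and Nfe2l2 changed by 0.13 ± 0.10 SE and 0.18 ± 0.16 SE and did not pass, while 4 of 7 NRF2 pathway regulators rose and 0 fell (4 adjusted over the list alone; adjusted p = 0.0764 with an estimated correlation). Within run A the log2 changes of Akr1b8, Nqo1 and Krt19 were 3.19, 2.62 and 1.53, the last of which did not pass (adjusted p = 0.0631 by limma), and within run B 6.16, 4.46 and 4.49.

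Obp3 was 8.79-fold lower under the negative label (log2 change −3.14 ± 0.52 SE), Aox3 6.78-fold and Cdh17 6.76-fold. Cyp2c11 was 3.32-fold lower (−1.73 ± 0.58 SE), which no longer passed with the set block (adjusted p = 0.102 by limma), within run A (−1.46, adjusted p = 0.0561 by limma), by neqc (adjusted p = 0.0733 by limma), without controls 25 to 27 (adjusted p = 0.0583 by limma) or without the nodule of replicate 15 (adjusted p = 0.0689 by limma). Of 23 extracellular matrix genes 14 rose and 1 fell (16 and 2 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation), with Col1a2 3.44-fold higher. Biliary and progenitor markers rose in 6 of 13 cases (8 adjusted over the list alone), Cd24 by 6.08-fold, and that list had an adjusted p = 0.0923 with an estimated correlation. Amino acid catabolism and the urea cycle had 6 of 20 genes lower and 0 higher (10 lower adjusted over the list alone), among them histidase (Hal), 2.91-fold lower (−2.04 within run B, and −0.72 within run A, where it did not pass, adjusted p = 0.0856 by limma). The list turned within set 1 (adjusted p = 0.935), and the adjusted p = 0.387 with an estimated correlation. The fit called 2633 genes (1325 higher, 1308 lower), 2279 with the run as a block, 1529 with the set block and 5618 with array weights. Within runs the count parted widely, at 1092 in run A and 5287 in run B, and at 358 within set 1 and 4215 within set 2. Lists that passed numbered 19, and 18 of these passed with the set block; within set 1 lists that passed numbered 9.

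Between the nodule labels 0 genes passed over all 20 nodules (limma), against 224 at an unadjusted p under 0.05, and neqc likewise gave 0 passing genes. Krt19 differed by −0.36 ± 0.70 SE (positive minus negative label, 10 and 10 nodules), Gstp1 by 0.58 ± 0.38 SE (0.06 ± 0.19 SE without KRT19-negative nodule replicate 8, with most nodules near the upper limit of the arrays), Nqo1 by 0.06 ± 0.30 SE and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, by −0.06 ± 0.31 SE. Afp, Nfe2l2 and Keap1 differed by −0.16 ± 0.29 SE, −0.11 ± 0.16 SE and 0.12 ± 0.10 SE. Weighting arrays by quality gave 32 genes and 25 lists, with NRF2 targets turned to lower under the positive label (adjusted p = 0.000817). In the pooled fit without weights 3 of 33 lists passed, with medians of −0.14 for extracellular matrix, 0.07 for NRF2 targets and 0.10 for cholesterol synthesis, and 0 members of any of them passed over all genes (3 NRF2 targets rose adjusted over the list alone). All 3 had an adjusted p = 0.996 with an estimated correlation. The run block and the set block each gave 0 genes and 3 lists. Lists numbered 1 without KRT19-positive nodule replicate 3 or 4, and 6 without KRT19-negative nodule replicate 8.

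The pooled value covered large and opposite differences within the runs. Within run A 1648 genes passed between the labels (889 higher and 759 lower under the positive label, 5 and 5 nodules), and within run B 3143 passed (1483 higher, 1660 lower). All 1310 genes that passed in both runs changed in opposite directions, and the log2 differences of the runs correlated across 13479 features at r = −0.874 (Spearman rho = −0.729; genes are not independent replicates). Krt19 was 6.31-fold higher under the positive label in run A (log2 2.66 ± 0.46 SE) and 10.3-fold lower in run B (−3.37 ± 0.44 SE). Of 32 NRF2 targets 19 were higher and 0 lower in run A, and 3 were higher and 25 lower in run B (adjusted p = 0.0901 and 0.139 with an estimated correlation). Nqo1 was 3.26-fold higher in run A and 3.00-fold lower in run B, and Gclc 2.68-fold higher and 2.92-fold lower. Cytochrome P450 genes went the other way, with 2 higher and 16 lower of 22 in run A and 17 higher and 1 lower in run B (adjusted p = 0.0780 and 0.139 with an estimated correlation). The same held for amino acid catabolism and the urea cycle, with 8 of 20 genes lower in run A and 17 higher in run B (adjusted p = 0.0901 and 0.139 with an estimated correlation). Genes with the largest interaction, chosen after their values were seen, included the neurofilament gene Nefl (19.3-fold higher in run A, 33.7-fold lower in run B), the drug pump Abcb1b (9.37-fold higher, 7.64-fold lower) and the aspartic protease Ctse (7.29-fold higher, 8.97-fold lower). Among those of opposite sign were Cyp8b1 (6.73-fold lower in run A, 3.73-fold higher in run B), Cyp4a2 (7.45-fold lower, 3.02-fold higher) and Cyp2c11 (5.04-fold lower, 2.86-fold higher). The interaction of label and run passed for 3976 genes (2117 with a higher label difference in run A, 1859 with a lower one; limma).

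**Figure D2:**
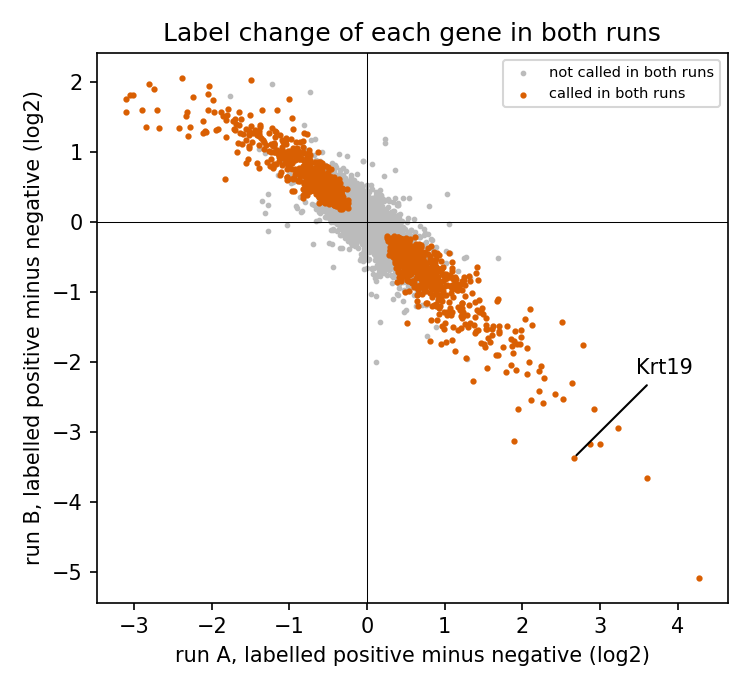
Log2 difference between nodules labelled KRT19-positive and KRT19-negative for each of 13479 features, in run A (horizontal axis) against run B (vertical axis). Orange points are the 1310 features that passed in both runs, all of them in the quadrants of opposite sign; Krt19 is marked.

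Detoxifying enzymes stood far above control liver in adenomas. Akr1b8 was 89.2-fold higher (log2 change 6.48 ± 0.76 SE, 4 and 10 arrays, adjusted p = 2.06e-08 by limma), Gstp1 81.1-fold (6.34 ± 0.50 SE), Car2 61.7-fold (5.95 ± 0.65 SE) and the glutathione transferase Gsta3 41.9-fold. Nqo1 rose 25.4-fold, Gclc 12.3-fold and Krt19 19.3-fold (4.27 ± 0.92 SE). Defb1, detected in 4 of 4 adenomas and no control, was at least 50.8-fold higher. Of 32 NRF2 targets 27 rose and 0 fell (27 adjusted over the list alone), with an adjusted p = 0.0361 with an estimated correlation, whereas Keap1 (0.24 ± 0.14 SE) and Nfe2l2 (0.29 ± 0.21 SE) did not pass. In cell cycle and proliferation 29 of 34 genes rose and 0 fell (30 adjusted over the list alone; adjusted p = 0.0870 with an estimated correlation), including the mitotic kinase Cdk1 (5.17-fold) and Ccnb2 (5.71-fold).

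On the lower side of the adenomas stood Obp3 (22.7-fold, log2 change −4.50 ± 0.68 SE), Mup4l3 of the same family (19.7-fold), Dhrs7l1 (15.6-fold) and the P450 genes Cyp4a2 and Cyp1a2 (13.3-fold each). Of 20 genes of amino acid catabolism and the urea cycle 17 fell and 0 rose (19 adjusted over the list alone; adjusted p = 0.0870 with an estimated correlation), among them serine dehydratase (Sds, 10.7-fold) and ornithine aminotransferase (Oat, 8.86-fold). Gluconeogenesis had 7 of 8 genes lower and 0 higher (7 adjusted over the list alone; adjusted p = 0.0870 with an estimated correlation), with Pck1, its rate-limiting enzyme, 6.77-fold lower. Among 22 drug-metabolizing P450 genes 15 fell and 2 rose (16 and 2 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation), and Cyp2c12 rose 15.5-fold. Onecut1, a hepatocyte transcription factor, was 7.99-fold lower, 1 of 9 members of its list of 16 that fell while 0 rose (9 adjusted over the list alone; adjusted p = 0.0870 with an estimated correlation). Housekeeping genes rose in 8 of 14 cases with 0 falls (10 adjusted over the list alone; adjusted p = 0.0870 with an estimated correlation). Their mean log2 intensity was above control (12.94) in every lesion group, from 13.14 in nodules labelled KRT19-positive to 13.49 in eHCC. In all 3510 genes passed (1818 higher, 1692 lower), 2606 with the run as a block, 2047 within run C, 2725 with the set block and 3284 within set 4, which holds 3 controls. Lists that passed numbered 20, of which 18 passed with the set block, when the thyroid hormone and p53 lists did not.

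Early carcinomas differed from control liver in much the same leading genes. Akr1b8 was 97.2-fold higher (log2 change 6.60 ± 0.70 SE, 5 and 10 arrays, adjusted p = 1.35e-09 by limma), Gstp1 81.3-fold (6.34 ± 0.46 SE), Gsta3 48.5-fold and Krt19 22.9-fold (4.52 ± 0.86 SE). Defb1 was detected in 5 of 5 eHCC and no control, at least 60.2-fold higher. NRF2 targets rose in 27 of 32 cases and fell in 1 (28 and 1 adjusted over the list alone; adjusted p = 0.0508 with an estimated correlation). Tgfb2, a growth factor on the YAP list that was detected in no control, was at least 2.14-fold higher; 5 of 9 YAP targets rose and 0 fell (6 adjusted over the list alone; adjusted p = 0.0933 with an estimated correlation). Of 23 matrix genes 16 rose and 3 fell (17 and 3 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation), with the fibulin Fbln1 7.12-fold and Col1a2 5.66-fold higher. Cdk1 rose 4.65-fold, 1 of 28 of 34 cell cycle genes that rose while 0 fell (29 adjusted over the list alone; adjusted p = 0.0753 with an estimated correlation).

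Falls in eHCC included urinary-type globulins and P450 enzymes. Mup4l3 was 82.5-fold lower (log2 change −6.37 ± 0.72 SE), Cyp2c11 72.6-fold (−6.18 ± 0.70 SE), Obp3 59.4-fold (−5.89 ± 0.63 SE) and the carbonic anhydrase Car3 32.1-fold (−5.00 ± 0.69 SE). Cyp2c7 was 53.3-fold lower by its brightest probe, but its other probe changed by −0.61. Slc27a5 was 28.5-fold and Sds 13.9-fold lower. Of 22 P450 genes 16 fell and 2 rose (16 and 2 adjusted over the list alone; adjusted p = 0.0933 with an estimated correlation). Of 20 genes of amino acid catabolism 19 fell and 0 rose (19 adjusted over the list alone; adjusted p = 0.0753 with an estimated correlation), and all 8 of gluconeogenesis fell (8 adjusted over the list alone; adjusted p = 0.0692 with an estimated correlation), Pck1 by 11.3-fold. Afp, the oncofetal albumin homolog, was 2.15-fold lower (−1.11 ± 0.35 SE, adjusted p = 0.0119 by limma), and did not pass with the set block (adjusted p = 0.0623 by limma), with the run block (adjusted p = 0.0607 by limma) or within run C. Keap1 changed by 0.28 ± 0.13 SE (adjusted p = 0.0876, 0.0422 with the set block and 0.0434 without control liver replicate 13, by limma) and Nfe2l2 by 0.40 ± 0.20 SE, which did not pass. A total of 4336 genes passed (2295 higher, 2041 lower), 3309 with the run as a block, 2679 within run C, 3452 with the set block and 4026 within set 4. Lists that passed numbered 24, none with an estimated correlation and 21 with the set block; the 3 that did not were p53 targets, perivenous genes, and immediate early and heat shock genes.

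Advanced carcinomas kept the rise of detoxifying enzymes over control. Gstp1 was 71.3-fold higher (log2 change 6.16 ± 0.39 SE, 9 and 10 arrays, adjusted p = 5.88e-16 by limma), Akr1b8 50.9-fold (5.67 ± 0.59 SE), the glutathione peroxidase Gpx2 24.7-fold (4.62 ± 0.39 SE), Nqo1 13.3-fold (3.73 ± 0.31 SE) and Gclc 5.07-fold (2.34 ± 0.32 SE). Krt19 was 14.0-fold higher (3.80 ± 0.72 SE) and Defb1, detected in 9 of 9 aHCC and no control, at least 38.0-fold. Of 32 NRF2 targets 28 rose and 1 fell (28 and 1 adjusted over the list alone; adjusted p = 0.0674 with an estimated correlation). Of 34 cell cycle genes 30 rose and 0 fell (31 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation), with Cdk1 5.63-fold and Ccnb2 4.16-fold higher. Glycolysis had 8 of 13 genes higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), including aldolase A (Aldoa, 2.53-fold) and the lactate exporter Slc16a3 (2.20-fold; adjusted p = 0.0559 by limma within run C). Biliary and progenitor markers rose in 8 of 13 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), Cd24 by 5.02-fold.

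Falls in aHCC included Mup4l3 (68.3-fold, log2 change −6.09 ± 0.61 SE), Cyp2c11 (65.9-fold, −6.04 ± 0.59 SE), Obp3 (49.6-fold, −5.63 ± 0.53 SE), Car3 (30.6-fold), the hydroxyacid oxidase Hao2 (12.5-fold) and Cyp3a2 (10.5-fold). Of 22 genes of complement and coagulation 18 fell and 0 rose (19 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation). Amino acid catabolism had 19 of 20 genes lower and 0 higher (19 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), among them Agxt, which clears glyoxylate, at 5.27-fold. In fatty acid synthesis 11 of 14 genes fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation); the desaturase Fads2 was 4.98-fold lower and Scd2 5.46-fold higher. All 8 genes of gluconeogenesis fell (8 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), the phosphatase G6pc1 by 6.87-fold. Keap1 (0.22 ± 0.11 SE), Nfe2l2 (−0.16 ± 0.17 SE) and Afp (−0.11 ± 0.29 SE) did not pass. Keap1 passed without control liver replicate 13 (0.27, adjusted p = 0.0433 by limma) or without aHCC replicate 36 (0.30, adjusted p = 0.0129 by limma), and Afp was lower without aHCC replicate 36 (−0.51, adjusted p = 0.0322 by limma). The fit called 5120 genes (2592 higher, 2528 lower), 5682 without aHCC replicate 29, 4204 with the run as a block and 3406 within run C. With the set block 2077 passed, 1962 of them shared with the pooled calls, and 1075 passed within set 3 against its 3 controls. The small heat shock protein Hspb1, 2.51-fold higher in the pooled fit, did not pass with the set block (adjusted p = 0.174 by limma). All 20 lists that passed also passed with the set block, and none with an estimated correlation.

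**Figure D3:**
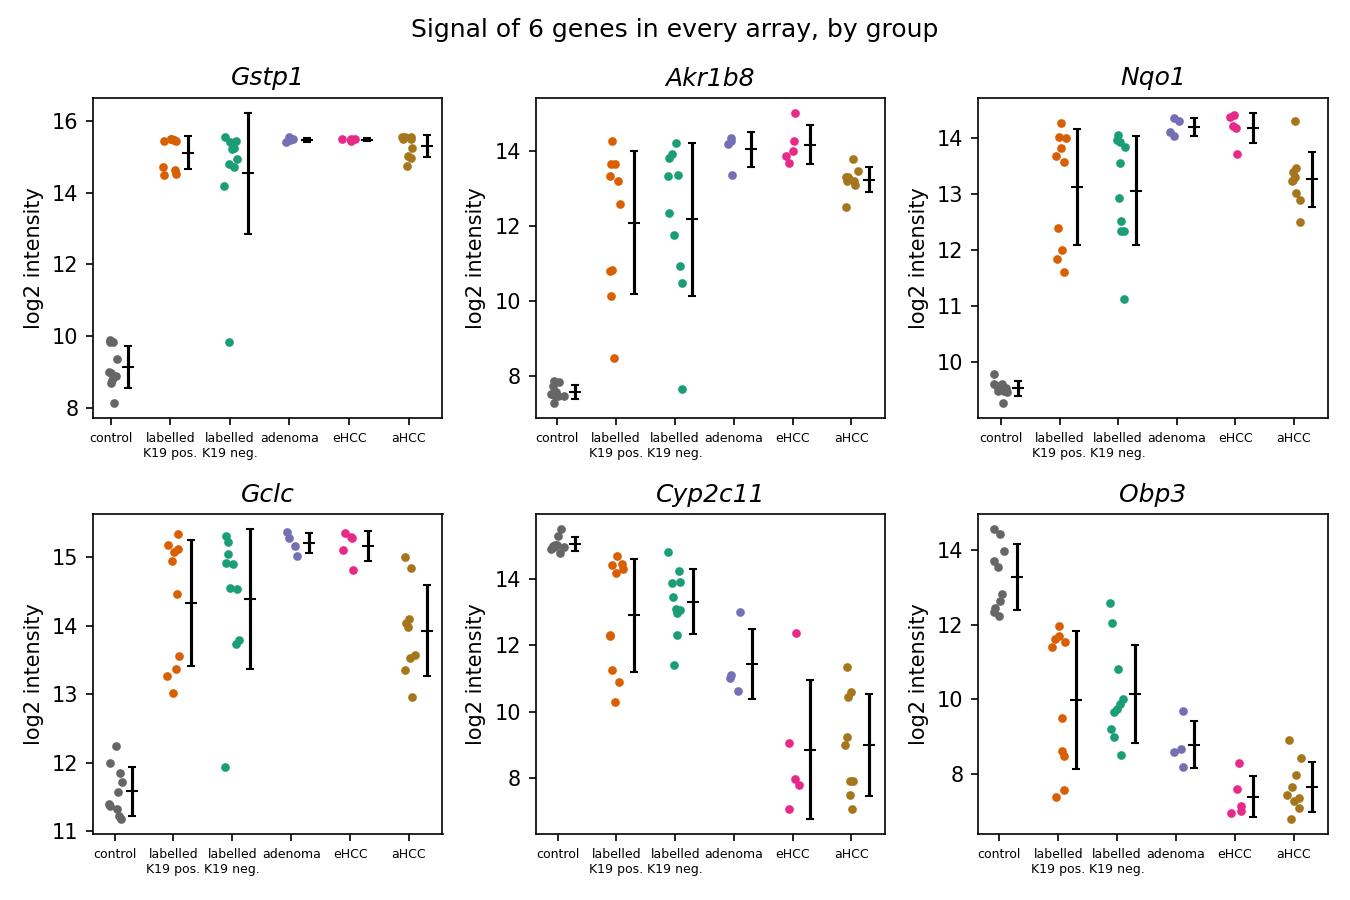
Log2 intensity (vertical axis) of Gstp1, Akr1b8, Nqo1, Gclc, Cyp2c11 and Obp3 in every array, by group (horizontal axis; K19 pos. and K19 neg. are the nodules labelled KRT19-positive and KRT19-negative). Points are arrays and bars are the mean ± SD; Gstp1 in lesions crowds below 15.54, the highest intensity of any probe, and 1 nodule labelled KRT19-negative (replicate 8) sits at 9.84 among the controls.

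**Figure D4:**
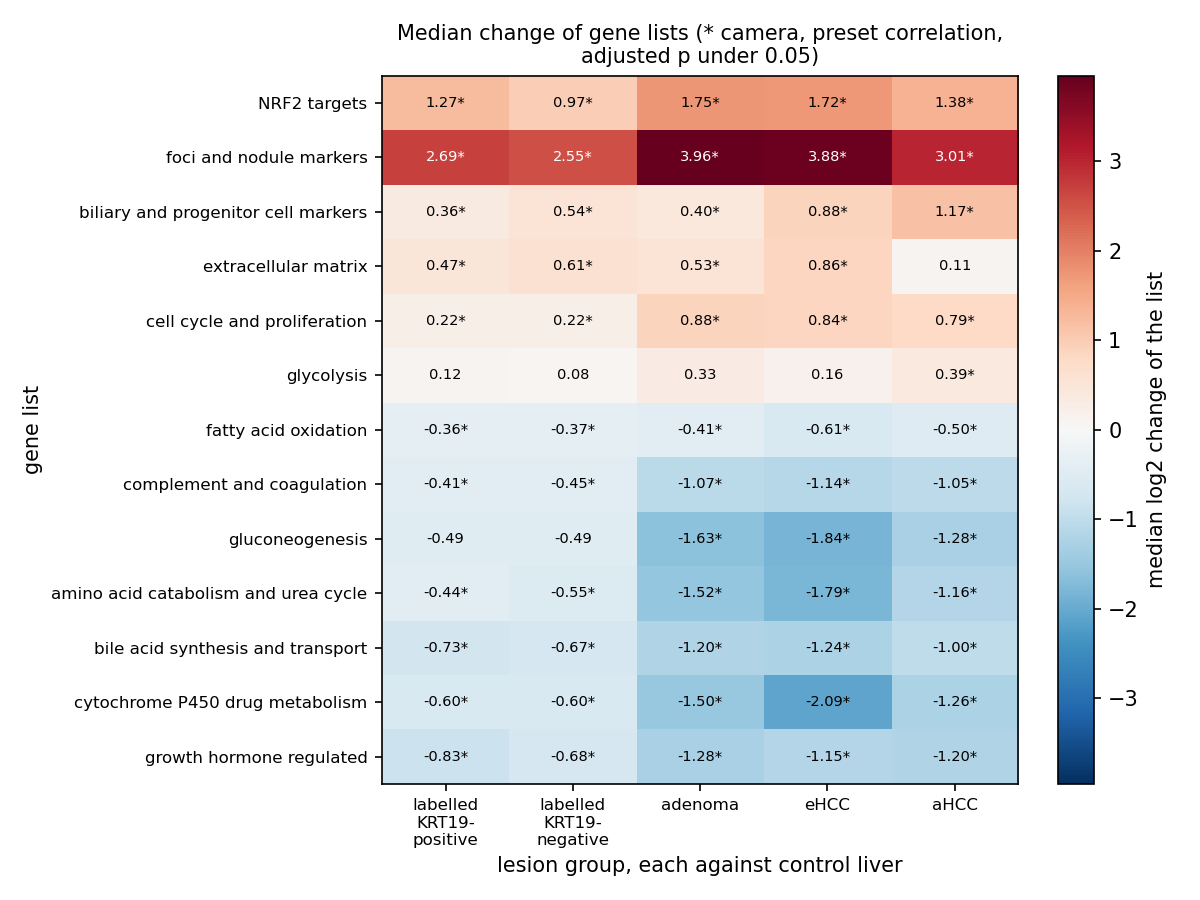
Median log2 change of 13 gene lists (vertical axis) in each lesion group against control liver (horizontal axis; the first 2 columns are the nodules by label). Red is higher and blue lower than control, numbers give the medians, and an asterisk marks an adjusted p under 0.05 by camera at its preset correlation, most of which did not pass with an estimated correlation.

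Early carcinoma and adenoma, both taken at 10 months, could not be told apart gene by gene. Between eHCC and adenoma 0 genes passed (limma, 5 and 4 arrays), against 173 at an unadjusted p under 0.05, with 0 also by neqc and with either block. Cyp2c11 was lower in eHCC by a log2 change of −2.58 ± 0.86 SE and Krt19 higher by 0.24 ± 1.05 SE, neither of which passed. Nqo1 (−0.02 ± 0.45 SE), Afp (−0.19 ± 0.43 SE), Nfe2l2 (0.11 ± 0.24 SE) and Keap1 (0.04 ± 0.15 SE) did not pass either, and Gstp1 and Gclc were near the upper limit of the arrays in both groups, so a difference could not be read. Of 33 lists 8 passed, with P450 genes at a median of −0.36 and matrix genes at 0.16, although 0 of their members passed over all genes or adjusted over the list alone; with an estimated correlation these lists had an adjusted p = 0.630 and 0.830. The 8 lists became 0 without eHCC replicate 39, 4 with array weights, and 4 without adenoma replicate 37 or 43.

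Advanced against early carcinoma gave 2134 genes (994 higher, 1140 lower in aHCC; limma, 9 and 5 arrays), 1230 with only the 2 groups fitted and 3803 with array weights, but the groups lie in different sets of 12. Rhoa, a small GTPase of the cytoskeleton, was 7.85-fold lower in aHCC (log2 change −2.97 ± 0.38 SE, adjusted p = 5.16e-07 by limma) and the RNA helicase Ddx6 6.64-fold lower (−2.73 ± 0.35 SE). With the set block their changes shrank to −0.08 ± 0.26 SE and −0.19 ± 0.28 SE. Controls 25 to 27, which share the numbers 25 to 36 with the aHCC, had the same low Rhoa intensity, and all 12 of these arrays lay at 8.77 to 10.22 against 12.05 to 13.26 in the other 36. Akr1c12, 4.55-fold lower by its brightest probe, changed by −0.15 by its other probe. Igfbp2, which binds insulin-like growth factors, was 5.24-fold higher (2.39 ± 0.45 SE; 0.91 ± 0.65 SE with the set block).

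Some matrix genes were lower in aHCC than in eHCC when pooled, and none of those named here passed with the set block. Col1a2 was 3.41-fold lower in aHCC (log2 change −1.77 ± 0.34 SE; −1.86 ± 0.61 SE with the set block, adjusted p = 0.277 by limma) and Fbln1 2.77-fold lower (−1.47 ± 0.41 SE; −1.86 ± 0.72 SE). Of 23 matrix genes 10 fell and 1 rose (12 and 2 adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). Of 32 NRF2 targets 6 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress responses 7 rose and 0 fell (7 adjusted over the list alone; adjusted p = 0.434 with an estimated correlation), with Sdf2l1 and Ddit3 both 1.70-fold higher. Macrophage markers rose in 4 of 14 cases with 0 falls (4 adjusted over the list alone; adjusted p = 0.658 with an estimated correlation), Marco by 3.63-fold and Vsig4 by 3.42-fold (adjusted p = 0.0622 by limma with only the 2 groups). Gclc (−1.24 ± 0.39 SE), Nfe2l2 (−0.57 ± 0.20 SE) and Afp (1.00 ± 0.36 SE) passed with an adjusted p = 0.0245, 0.0478 and 0.0483 by limma. Gclc no longer passed without aHCC 33 or without eHCC 40, 44 or 45; Nfe2l2 without aHCC 29, 32, 33, 35 or 36 or any 1 eHCC; and Afp without aHCC 28, 30, 32, 33, 35 or 36 or any 1 eHCC. Krt19, Nqo1 and Keap1 (−0.71 ± 0.87, −0.92 ± 0.38 and −0.06 ± 0.13 SE) did not pass. Gstp1 was at or near the upper limit of the arrays in eHCC (15.44 to 15.51) and in aHCC 31 to 36 (15.26 to 15.54). It lay lower in aHCC 28 to 30 (14.74 to 15.03), and the size of a group difference could not be read. Afp and Nfe2l2 also did not pass with only the 2 groups (adjusted p = 0.315 and 0.126 by limma) or within run C (adjusted p = 0.196 and 0.103 by limma), nor did Ddit3 (adjusted p = 0.175 and 0.101 by limma). Nqo1 was lower without aHCC replicate 29 (−1.05, adjusted p = 0.0378 by limma), with only the 2 groups (adjusted p = 0.0212 by limma) and within run C (adjusted p = 0.00397 by limma), and Ddit3 did not pass without eHCC replicate 39 (adjusted p = 0.0624 by limma). The run as a block gave 2224 genes, run C alone 1727 and the set block 1 gene, while 3085 passed without aHCC 29. Array weights gave 13 lists. Of 6 lists that passed 4 also passed with the set block, where the P450 and macrophage lists had an adjusted p = 0.0836 and 0.362. Lists numbered 12 without aHCC 29 and 4 without aHCC 31.

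**Figure D5:**
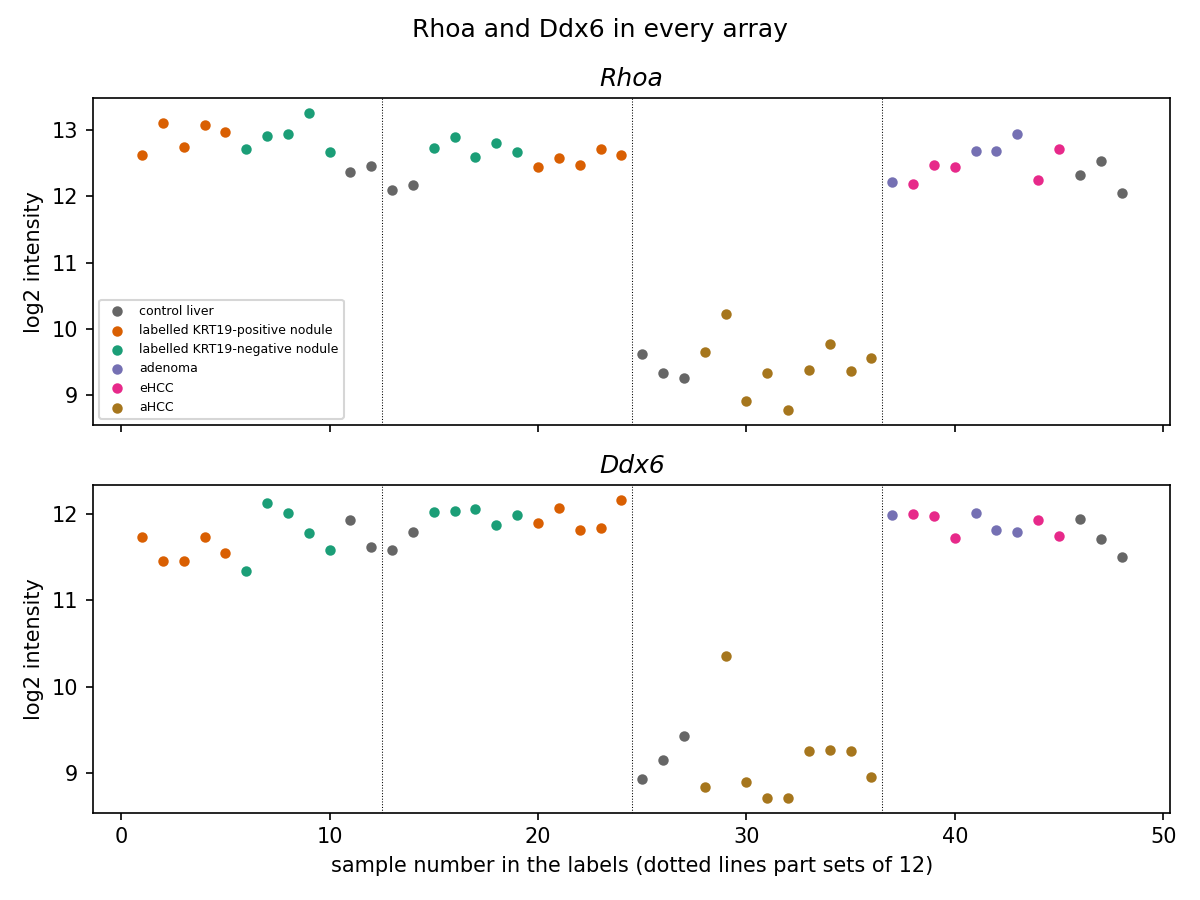
Log2 intensity (vertical axes) of Rhoa and Ddx6 in each of 48 arrays, by sample number (horizontal axis), coloured by group, with dotted lines between sets of 12. Arrays 25 to 36, which are 3 controls and 9 aHCC, lie below all others in both panels.

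Against nodules labelled KRT19-positive, aHCC in the pooled fit showed more blood, proliferation and lymphocyte transcripts and fewer of hepatocyte metabolism. Of the 14 lists that passed 7, the blood cell list among them, did not pass with the set block, and none passed with an estimated correlation. The haemoglobin chains Hbb-b1 and Hba-a1 were 6.05-fold and 3.61-fold higher in aHCC (log2 changes 2.60 ± 0.32 and 1.85 ± 0.23 SE, 9 and 10 arrays, adjusted p = 9.73e-08 and 1.20e-07 by limma), and 5 of 10 blood cell markers rose with 0 falls (5 adjusted over the list alone; adjusted p = 0.445 with an estimated correlation). Esm1, an endothelial proteoglycan, was 3.78-fold higher (1.92 ± 0.16 SE) and still passed with the set block (1.94 ± 0.31 SE, adjusted p = 0.000656 by limma). Of 34 cell cycle genes 22 rose and 0 fell (24 adjusted over the list alone; adjusted p = 0.445 with an estimated correlation), with Cdk1 3.29-fold and Prc1, of the mitotic spindle, 2.10-fold higher. Lymphocyte markers rose in 9 of 18 cases with 0 falls (9 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation). Mup4l3 was 16.4-fold lower (−4.03 ± 0.61 SE, no longer passing with either block), Cyp2c11 15.0-fold (−3.90 ± 0.59 SE) and Sds 8.45-fold. Of 20 genes of amino acid catabolism 11 fell and 0 rose (11 adjusted over the list alone; adjusted p = 0.491 with an estimated correlation), and of 14 of fatty acid synthesis 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.445 with an estimated correlation), the desaturase Fads1 by 4.02-fold.

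NRF2 targets did not pass as a list between these groups, with 2 of 32 higher and 4 lower (2 and 4 adjusted over the list alone; adjusted p = 0.958, and 0.986 with an estimated correlation). The nodules differed among themselves: mean log2 Nqo1 under the positive label was 13.96 in run A and 12.29 in run B, against 13.26 in aHCC. Gstp1 lay at 14.51 to 14.71 in nodules 20, 21, 22 and 24 and at 15.45 to 15.51 in the other nodules of that label. In aHCC it lay at 14.74 to 15.03 in replicates 28 to 30 and at 15.26 to 15.54 in the others. Many of these arrays were near the upper limit, so a difference between the groups may be understated. Krt19 differed by 1.06 ± 0.72 SE, Nqo1 by 0.14 ± 0.31 SE, Gclc by −0.40 ± 0.32 SE and Afp by 0.63 ± 0.29 SE, none of which passed, nor did Nfe2l2 (−0.24 ± 0.17 SE) or Keap1 (−0.02 ± 0.11 SE). Afp passed without aHCC replicate 29 (0.85, adjusted p = 0.0151 by limma). In total 3353 genes passed (1740 higher, 1613 lower), and 4229 without aHCC 29. No set of 12 and no run held both groups, so no value within a batch could be had; only the controls link the batches. With the run as a block 1931 genes passed and 8 of the lists, with array weights 9 lists, and with the set block 10 genes and 7 lists of the 14, among them cell cycle and lymphocyte markers. The lists lost were blood cell markers, glycolysis, gluconeogenesis, fatty acid oxidation, bile acid synthesis and transport, complement and coagulation, and hepatocyte transcription factors (adjusted p = 0.146, 0.0794, 0.0844, 0.214, 0.112, 0.0844 and 0.910), the last of which turned in direction. Cyp2c11 then changed by −3.66 ± 1.14 SE (adjusted p = 0.206 by limma), Cdk1 by 1.96 ± 0.54 SE (adjusted p = 0.134) and Rhoa, 9.79-fold lower when pooled, by −0.42 ± 0.23 SE.

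Genes that changed in aHCC were then sought in the nodules. Of the 5120 genes that passed between aHCC and control, 1700 (33.2%) passed in the same direction in nodules labelled KRT19-positive (862 higher, 838 lower; 73 opposite) and 1731 (33.8%) in nodules labelled KRT19-negative (858 higher, 873 lower; 76 opposite). Independent lists of these sizes would share 9.34% and 9.77%, and unchanged groups simulated against shared controls gave 0 shared calls in 20 runs; neither figure accounts for effects and shared controls together. Log2 changes of aHCC and nodules correlated across genes at r = 0.762 and 0.754 against 0.487 in the simulation, with covariances of 0.157 and 0.151 against 0.00838. With separate controls for each side the shares were 19.9% and 18.7%, and 24.9% and 24.6% with the controls exchanged. Within run A 47.0% was shared by nodules labelled KRT19-positive and 13.7% by those labelled KRT19-negative, and within run B 17.0% and 44.8%. Array weights gave 38.3% and 54.9%, and only the groups compared 46.7% and 43.2%.

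On the signature score, which is 0 at the control mean and 1 at the aHCC mean, nodules labelled KRT19-positive averaged 0.537 ± 0.278 (SD, n = 10) and those labelled KRT19-negative 0.514 ± 0.266 (SD, n = 10), a difference of 0.0225 (two-sided permutation test, p = 0.854; 3 tests in this family, adjusted p = 0.854). Within run A the label difference was 0.490 (0.784 ± 0.0784 against 0.294 ± 0.152, SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0119). Within run B it was −0.445 (0.290 ± 0.126 against 0.735 ± 0.121, SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0119). Both p-values are the smallest that 5 nodules against 5 allow.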

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

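The explanation tests and split counts in this part, and the choice of sets of 12 and of controls 25 to 27, were set down after the values had been seen; the values within runs were planned.

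In the nodules the effect of the KRT19 label differed between runs A and B for 3976 genes by a test of the interaction (limma), and for Krt19 the difference was 6.03 on the log2 scale. Exchanged labels within one of the runs and truly opposite biology of the nodules are not told apart by the mirrored label changes (r = −0.874 across genes), which restate the pattern. Krt19 itself argues against correct labels in run B, at 7.70 to 10.60 under the positive and 11.49 to 12.96 under the negative label. That reading needs the transcript to follow the KRT19 status behind the labels, and how that status was assigned was not given. Labels also followed sample order, with the higher Krt19 in the first 5 nodules of each run. An effect tied to that order within each run, such as shared animals, would also give the mirror and was not tested. A shift common to all arrays of a run is excluded as the cause, because it cancels between the labels within the run. The 3143 genes that passed within run B alone are part of the pattern, so they add no test. A misread Krt19 probe with correct labels is excluded too, because 100% of the 1310 genes that passed in both runs changed in opposite directions. By the Krt19 transcript, which followed the label in run A and went against it in run B, an exchange would lie in run B. Chance among independent nodules is excluded as the source of the split within run A (1648 genes, highest other split 72) and within run B (3143, highest other 1815). The same holds for the interaction (3976, highest other 3). In each, 1 of 100 splits, the real one, reached the value. Nodules may share a rat and the labels do not tie them to animals, so the splits do not exclude a difference between animals.

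Controls 25 to 27 differed from the 7 other controls in 710 genes (352 higher, 358 lower), and chance is excluded, with 1 of 100 splits as large and 31 genes in the highest other. A batch of arrays 25 to 36 may explain it, since the change of these controls against controls 11 to 14 correlated with that of aHCC against eHCC (r = 0.405; −0.0252 for controls 46 to 48 against 11 to 14). With all controls r was 0.451, and 1 of 120 choices of 3 controls reached it, the real one (next 0.410). The aHCC stage alone is excluded as the whole cause by the same 710 genes, which passed between control livers. Age or handling of the rats behind these controls cannot be told apart from a batch: in 1 of 4 moved genes (25%, 95% interval 0.631 to 80.6%) the other probe followed, against 11 of 11 for aHCC minus the same controls (Fisher exact p = 0.00879), and 4 genes are too few.

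Advanced carcinoma replicate 29 stood apart, with 218 genes at least 4-fold above and 300 at least 4-fold below every other aHCC, against at most 12 and 0 for any other. Poor RNA or weak labelling is excluded as the whole cause by 203 of the 218 genes with a log2 intensity of at least 10. Even dilution by a tissue without complement and coagulation transcripts is excluded. The test took such genes clear of background (mean of at least 10) and more than 0.5 below the upper limit of the arrays. Of 14 genes 5 were less than 2-fold below the mean of the other aHCC, among them F5 (2.45 above). Another 8 were at least 4-fold below, Serpind1 by −6.26. A tissue that expresses some of these genes is not excluded by the test. That test took the place of one on secretory genes, in which the 3 genes not below that mean (Alb, Tf and Apoe) lay near the upper limit. A sample wholly from outside the liver would need low Alb. Alb lay at 15.41, above the 14.39 to 14.99 of the other aHCC (0.73 above that mean), which argues against it. Its place within 0.5 of the upper limit can hide an excess but not a fall. Apoa2, Apoc1 and Ttr were far from that mean the other way (−6.38, −5.85 and −4.155), so how much liver the sample held stays open. Of 14 genes of gastric and intestinal epithelium, listed only after this array was seen to stand apart, 5 were at least 4-fold above every other aHCC, among them Tff1 (13.98, highest other 7.36), Ctse (14.04, highest other 10.51) and Gkn2 (12.60, highest other 7.50), while Cdh17 (7.37) and Reg4 (7.05) lay below the mean of the other aHCC (9.21 and 8.28). A differentiation of this lesion toward gastric epithelium may underlie the pattern as a hypothesis; it was not tested, and an uneven mixed sample stays open.

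A further 34 values lay far from the rest of their group by Dixon's test, out of 256 sets tested, where chance alone gives about 1 in 20, or 12.8. Of these 13 belonged to aHCC 29: Defb1 15.06, Gsta3 10.18, Cyp3a2 7.20, Agxt 7.12, G6pc1 7.52, Slc27a5 7.77, Ddx6 10.35, Ugt2b1 7.13, Vsig4 6.97, S100a6 14.98, Fads1 7.60, Thrsp 7.30 (log2 intensity) and 8689 detected probes. In the nodule of replicate 8, labelled KRT19-negative, Gstp1 (9.84), Akr7a3 (10.81), Gclc (11.93) and Gstm1 (14.06) were low and Aox3 (10.26) was high. Among controls these were Krt19 8.76, Cyp8b1 13.14 and Cyp2c7 14.62 in replicate 27, Angptl4 10.08 in replicate 26, Scd2 7.49 in replicate 25, Cyp2c12 8.80 and Hmox1 10.91 in replicate 14, and 8323 detected probes in replicate 48. In lesions they were Akr1b8 13.36 and Hao2 9.60 in adenoma 43, Keap1 10.10 in adenoma 37, Car2 13.73 in eHCC 38, Sdf2l1 7.75 in eHCC 39, Afp 13.94 and Igfbp2 12.56 in aHCC 36, and Igfbp2 9.91 in the nodule of replicate 4, labelled KRT19-positive.

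Other splits of the arrays into groups of the same sizes were tried 100 times per comparison. Chance is excluded for the gene counts of both nodule labels, adenoma, eHCC and aHCC against control (2517, 2633, 3510, 4336 and 5120 genes; highest other 399, 1075, 1450, 2742 and 959), for aHCC against eHCC (2134; 978) and against nodules labelled KRT19-positive (3353; 1281), and for aHCC against the controls of set 3 (1075; 205), each with 1 of 100 splits as large. The splits ignored the sets of 12 and any shared animal, so a batch or a difference between animals is not excluded by them. With the set block 1 gene passed for aHCC against eHCC and 10 for aHCC against nodules labelled KRT19-positive. Between the labels over both runs (0 genes by limma, 224 at an unadjusted p under 0.05) and between eHCC and adenoma (0 by limma, 173 at an unadjusted p under 0.05) all 100 splits had to reach the count, which says nothing about chance. The highest other split of the nodules gave 254 genes, which points to a structure among them; what that split parts was not tested, and for eHCC and adenoma it gave 74. For the lists, few splits reached the real count in nodules labelled KRT19-negative (19 lists, 2 of 100 splits, highest other 21, median other 4) against control. The same held for eHCC (24 lists, 3 of 100, highest other 24, median other 9) against control. Chance is not excluded there, since another split reached or passed each real count and the 9 comparisons were not adjusted for. It is likewise not excluded for nodules labelled KRT19-positive (18 lists, 7 of 100, highest other 22), adenoma (20, 5 of 100, 21) or aHCC (20, 12 of 100, 21) against control. Nor is it excluded between the labels (3, 63 of 100, 27), for eHCC against adenoma (8, 54 of 100, 20), aHCC against eHCC (6, 72 of 100, 17) or aHCC against nodules labelled KRT19-positive (14, 27 of 100, 27). The difference of 0.606 percentage points in the share of aHCC changes between labels was reached by 95 of 100 splits (highest other 29.8).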

How the results depend on the processing

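The set block, sets alone, neqc, aHCC 29 with the set block and controls 25 to 27 left out were chosen after the data had been seen; all other settings here were planned.

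The second deposited table was identical and 75th percentile scaling moved no log2 value by more than 0.00093, so neither could test anything. Normexp with an offset of 50 and neqc moved log2 values by up to 1.05 and 2.32. They changed the calls of 2 of 205 named gene results (both by neqc) and ended 3 (normexp) and 6 (neqc) of 132 list results that passed. Passing genes of at least 2-fold rose from 359 to 727 by neqc for nodules labelled KRT19-positive against control. The median of all genes shifted by at most 0.0144, which quantile normalization largely fixes. Values before the submitters' normalization were not at hand, so dependence on it was not tested. The run block ended 7 of the named gene calls and the set block 44, with 1 gained. The chip was not tried as a block, since no label names it. No paired analysis was possible because sample numbers are unique across groups. Signal over background limits the dim genes, whose folds are compressed. The cause of the changes below was not tested, except that estimated correlations widen the list tests, runs and sets alone hold fewer samples, and filters change the genes tested.

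Shares of aHCC changes in nodules labelled KRT19-positive and KRT19-negative were 29.6% and 29.9% with no filter, 37.0% and 37.9% with the strict filter (6 lists between labels), 24.5% and 24.1% with the run block, 37.3% and 36.2% with the set block, 42.8% and 41.6% also without aHCC 29, 31.9% and 31.3% without controls 25 to 27, and 19.9% and 18.7%, or 24.9% and 24.6%, with controls split. Array weights gave 5618 genes for the negative label against control, 32 between labels and 3803 for aHCC against eHCC. Their lists numbered 25 between labels, 4 for eHCC against adenoma, 13 for aHCC against eHCC and 9 for aHCC against nodules labelled KRT19-positive, with shares of 38.3% and 54.9%, and NRF2 targets turned lower under the positive label (adjusted p = 0.000817). Fitting only the groups compared gave shares of 46.7% and 43.2%, 6 lists between labels and 1230 genes for aHCC against eHCC.

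The run block gave 1931 genes and 8 lists for aHCC against nodules labelled KRT19-positive. Run A alone gave 1092 genes for the negative label against control, 1648 genes and 22 lists between labels, shares of 47.0% and 13.7% and a score difference of 0.490. Between labels it reversed Krt19 (2.66), Gclc (1.42), matrix genes (adjusted p = 0.0150) and cholesterol synthesis (adjusted p = 0.172). Run B alone gave 5287 genes for the negative label, 8 lists for the positive label, 3143 genes and 26 lists between labels, shares of 17.0% and 44.8% and a score difference of −0.445. It reversed NRF2 targets (adjusted p = 4.37e-11), Gstp1 (−0.51), Nqo1 (−1.58) and Afp (0.58) between labels, and Nfe2l2 under the positive label against control (−0.36). The controls for that Nfe2l2 value lie in set 3, and set 2 alone did not reverse it. Run C alone gave 2047, 2679 and 3406 genes for adenoma, eHCC and aHCC against control.

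An estimated correlation left 2 lists for each nodule label and 1 for adenoma against control, and 0 in the 6 other comparisons. The set block gave 1517 and 1529 genes for the labels against control, 2077 for aHCC, 1 for aHCC against eHCC, and 10 genes and 7 lists for aHCC against nodules labelled KRT19-positive, where hepatocyte transcription factors turned (adjusted p = 0.910; 0.902 also without aHCC 29). Without aHCC 29 that block gave 2653 genes for aHCC against control, 2 genes and 12 lists against eHCC, and 92 genes and 6 lists against nodules labelled KRT19-positive.

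Set 1 alone gave 358 genes and 9 lists for the negative label against control, 1545 genes and 23 lists between labels, shares of 35.9% and 5.14% and a score difference of 0.490. It reversed amino acid catabolism (adjusted p = 0.935), cell cycle and housekeeping (both 0.946) for the negative label, and between labels matrix genes (0.0174), cholesterol synthesis (0.189), Krt19 (2.66) and Gclc (1.42). Set 2 alone gave 1290 and 4215 genes for the labels against control, 3484 genes and 26 lists between labels, shares of 16.5% and 54.2% and a score difference of −0.445, with NRF2 targets (adjusted p = 2.11e-10), Gstp1 (−0.51), Nqo1 (−1.58) and Afp (0.58) reversed. Set 3 alone gave 1075 genes for aHCC against control.

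With 1 array left out, shares ranged from 28.2% (without replicate 5) to 36.1% (aHCC 29) for the positive label and from 27.7% (replicate 15) to 37.4% (replicate 8) for the negative, and the score difference from −0.0272 to 0.0672. Lists ranged from 1 (without replicate 3 or 4) to 6 (replicate 8) between labels, from 0 (eHCC 39) to 11 (eHCC 38) for eHCC against adenoma, with 4 without adenoma 37 or 43, from 4 (aHCC 31) to 12 (aHCC 29) for aHCC against eHCC, and from 10 to 14 for aHCC against nodules labelled KRT19-positive. Against control they ranged from 14 to 19 and 16 to 20 for the labels, 19 to 24 for adenoma, 23 to 24 for eHCC and 18 to 20 for aHCC. Genes ranged from 2084 to 2652 and 2124 to 2881 for the labels, 2678 to 3483 for adenoma, 3474 to 4263 for eHCC and 4850 to 5682 for aHCC against control, from 1564 to 3085 for aHCC against eHCC and from 2975 to 4229 against nodules labelled KRT19-positive, and stayed at 0 (limma) between labels and for eHCC against adenoma. Of 3542 single-gene values 27 lost and 10 gained a call, and 0 reversed.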

Other observations

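The lists of sex-biased genes in this part, and the test on them, were chosen after the results had been seen, and the male list was trimmed after a first run.

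Of 9 genes that rat liver expresses mainly in males, listed after several had been seen among the falls, 5 fell in nodules labelled KRT19-positive, 5 in nodules labelled KRT19-negative, 8 in adenomas, 9 in eHCC and 9 in aHCC, and 0 rose in any of these groups (limma). The median log2 change was −1.32, −1.12, −2.67, −4.06 and −2.80. As a list they did not pass at any stage with an estimated correlation (adjusted p = 0.249, 0.303, 0.166, 0.104 and 0.166). Cyp2c11, the main male P450 of rat liver, was 72.6-fold lower in eHCC and 65.9-fold lower in aHCC than in control liver.

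A change from a male to a female pattern of liver expression was a hypothesis for these falls, and it would need the female genes to rise together. Of 6 genes expressed mainly in females 2 rose in aHCC (Cyp2c12 by 3.07 ± 0.65 SE and A1bg by 0.76 ± 0.31 SE on the log2 scale) and 3 fell, with a median of −0.34 (adjusted p = 0.614). In eHCC 1 rose and 3 fell (adjusted p = 0.0472, and 0.249 with an estimated correlation). With members that moved both ways the test decided nothing, and the hypothesis stays open.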
